A study of Mus musculus with 5 samples.

How the data were processed

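Total RNA from frozen mouse liver had been made into sequencing libraries with the Illumina TruSeq RNA kit, per the labels' protocols. The values used are raw read counts per gene symbol as deposited by the authors, in 1 table per library with 24834 rows. That they are counts follows from the values, which are whole numbers with a different total in each library. The submitters' processing notes name Bowtie 0.12.2 and the genome builds mm8 and mm10, with no role for each. The counting program, the gene annotation and whether counting used strand are not given in the sources used here. Without strand, reads of overlapping genes on opposite strands cannot be told apart, and with short reads placed by Bowtie, reads of close paralogs can be lost or split.

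In each table, 26 rows carried a calendar date in place of a gene symbol, as spreadsheet programs make from names such as those of the septin genes. They held 0.144 to 0.169% of the counts and were left out. Library totals were 18634801 to 21773867 counts, and 34.2 to 35.8% of rows were 0. A count of 3, the upper limit that a count of 0 allows, corresponded to 0.135 to 0.156 CPM. Intervals on pooled counts are exact 95% intervals and cover counting error only, as reads without molecular identifiers are not independent molecules. No pair of libraries agreed within sampling noise, so no library repeats another. That does not show separate mice, and each counted as a replicate because the series design describes them as mice.

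Libraries were grouped by their treatment label, 3 CCl4 and 2 CCl4+givinostat. Replicate numbers came from the sample titles. The labels state no batch. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with its defaults, which left 13590, and libraries were scaled by trimmed mean of M values (TMM). A quasi-likelihood negative binomial model with treatment as its only term was fitted to all 5 libraries, leaving 3 residual degrees of freedom, and genes were called at a Benjamini-Hochberg adjusted p of 0.05. The common biological coefficient of variation was 20.0%. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and list scores use log2 CPM with a prior count of 2.

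In all, 56 gene lists covering matrix, stellate and other liver cell types, hepatocyte functions, immune processes and covariates were written before the data were examined, as were the tests, the alternatives and the rule for naming genes. The 53 lists with at least 5 tested members were tested with limma 3.58.1 camera on log2 CPM with a preset inter-gene correlation of 0.01, adjusted over the 53 lists. Pancreatic acinar, muscle and mitochondrially encoded lists had too few tested members. The count adjusted over a list alone applies Benjamini-Hochberg to the edgeR p-values of its members, and running that count under the alternatives was added after seeing the data. Single values carry an exact permutation test over the 10 assignments of 5 libraries, whose smallest p is 0.1.

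Genes were named by a rule. It took genes past the threshold whose groups did not overlap and whose higher group averaged at least 5 CPM, then the 5 smallest p-values in a direction with too few such genes, with no claim of change. It also took up to 4 members of each described list with the smallest p, the 8 fibrosis readouts and Hdac1 to Hdac11. Some genes that the rule takes are not reported here. Gene positions come from GENCODE M21 on GRCm38 (mm10), 1 of the 2 builds the submitters' processing notes name. Transcript length and GC content come from the same release and were matched by symbol for 98.9% of the tested genes.

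The alternatives were the replicate number as a block, relative log expression (RLE) scaling, no low-count filter, a stricter filter of at least 10 counts in every library of a group, each library left out in turn, DESeq2 1.42.0, an adjusted p of 0.1, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. The procedure was tested on simulated counts drawn from the real means, dispersions and library sizes, over 13368 genes. It called 40.2% of 97 genes changed 2-fold and 89.4% of 94 genes changed 4-fold, and 8.82% of its 136 calls were on unchanged genes. A list of 26 genes shifted by -0.5 (log2) got an adjusted p of 5.07e-07, and 2 of 40 lists with no changed member were called. In 12 further simulated sets with no change at all, 1 of 636 list tests passed and at most 5 genes were called in a set. Genes were drawn independently in all simulated sets, so these rates do not carry over to lists whose members move together. The estimated correlation in the real data was 0.906 for sinusoidal endothelial genes and 0.696 for cholesterol synthesis genes.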

Results

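Liver RNA was sequenced from C57BL/6 mice, aged 16 weeks per the labels, that had received carbon tetrachloride (CCl4), a hepatotoxin whose repeated use scars the rodent liver, or CCl4 together with givinostat. Givinostat inhibits histone deacetylases, the enzymes that remove acetyl groups from histone tails. The CCl4 group held 3 libraries and the CCl4+givinostat group held 2, which the series design describes as mice. The deposited tables are titled with 8 weeks, without saying what that counts, and dosing schedule, sex and feeding state are not given in the sources used here. Total counts were 21099040, 21065938 and 18634801 in CCl4 replicates 1, 2 and 3, and 21430125 and 21773867 in givinostat replicates 1 and 2. Albumin, the main secreted protein of hepatocytes, took 7.02 to 8.15% of the counts. In a principal component analysis of log2 CPM (counts scaled by library size), the first component (38.0% of the variance) set CCl4 replicate 1 apart from CCl4 replicates 2 and 3, and the second (30.6%) separated the treatment groups.

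The design implies a single comparison, CCl4+givinostat against CCl4, and the series title places it in the setting of liver fibrosis and the activation of hepatic stellate cells, the vitamin A-storing cells that become matrix-producing myofibroblasts in injured liver. With givinostat, genes of fatty acid oxidation lay higher, and genes of cholesterol synthesis, of mesothelial cells and of the collagen-rich matrix lay lower, as groups fixed before the data were examined. These 4 lists passed a test with a preset correlation between genes, and none passed with an estimated correlation (adjusted p = 0.538, 0.542, 0.538 and 0.663). Estimating the correlation also cuts that test to the 3 residual degrees of freedom, so the loss cannot be put down to correlation alone. The number of single genes past a test over all genes depended on the tool. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13590 genes, 1 gene rose and 0 fell, whereas 478 were higher and 534 lower at an unadjusted p under 0.05. Those at an unadjusted p under 0.05 were 7.45% of the genes. Splitting the 5 libraries differently gave 13.5% for CCl4 replicates 2 and 3 against the rest. It gave 12.5% for CCl4 replicate 1 with givinostat replicate 2 against the rest, and 1.10 to 5.21% in the remaining splits. The split that gave 13.5% keeps both givinostat libraries together, so a treatment difference can add to its share. DESeq2 called 69 genes higher and 79 lower. Without CCl4 replicate 1, edgeR called 119 and 116, and without any other library it called 0 in each direction.

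The gene that rose was Asic5, which encodes a bile acid-sensitive ion channel (chromosome 3, 81982290 to 82021233, plus strand, GRCm38). Asic5 averaged 3.09 ± 0.162 CPM (SD, n = 3) with CCl4 and 14.8 ± 1.15 CPM (SD, n = 2) with givinostat, a log2 fold change of 2.26 ± 0.20 (SE; edgeR adjusted p = 0.0416). Its adjusted p was 0.150 without CCl4 replicate 2, 0.0652 without CCl4 replicate 3, 0.838 without givinostat replicate 1, 0.324 without givinostat replicate 2 and 0.0509 with a stricter count filter, with the fold change between 2.18 and 2.34 throughout. Among genes whose groups did not overlap and whose higher group averaged at least 5 CPM, the next smallest edgeR p-values, none past edgeR's threshold, belonged on the higher side to Scd1, Lepr, Cyp4a10, Eif4ebp3 and Cidec, with log2 fold changes of 1.37 ± 0.15, 1.36 ± 0.17, 1.35 ± 0.18, 2.13 ± 0.29 and 1.92 ± 0.27 (SE). Lepr is the leptin receptor gene, and Cidec encodes a lipid droplet protein. On the lower side they belonged to Dnajc12, Fam222a, Noct, Idi1 and Cyp2c70, with log2 fold changes of -1.77 ± 0.18, -2.08 ± 0.30, -1.58 ± 0.24, -1.88 ± 0.30 and -1.23 ± 0.19 (SE). Scd1 and Dnajc12 came closest, each with an edgeR adjusted p of 0.0566. DESeq2 called all 10 of these genes over all genes, with its largest adjusted p at 1.45e-05 for Cyp2c70. EdgeR called them with no low-count filter or with the replicate number as a block. It called none of them with the stricter filter, without CCl4 replicate 2 or without CCl4 replicate 3. In the GENCODE annotation, 67.3% of the exonic bases of Eif4ebp3 overlap a longer same-strand gene model, so its reads cannot be assigned with certainty.

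Genes of fatty acid oxidation and ketogenesis moved together. All 31 measured members had a higher fitted value with givinostat, the median log2 fold change was 0.46, and 13 members rose when the p-values were adjusted over the list alone, against 0 when adjusted over all genes tested by edgeR. DESeq2 called 9 members higher over all genes. Cyp4a10, a fatty acid omega-hydroxylase induced through the nuclear receptor PPARα, averaged 3048 ± 60.0 CPM (SD, n = 2) with givinostat and 1195 ± 204 CPM (SD, n = 3) with CCl4. Acaa1b, a peroxisomal thiolase, averaged 3052 ± 7.68 CPM (SD, n = 2) against 1480.4 ± 258 CPM (SD, n = 3), a log2 fold change of 1.04 ± 0.18 (SE). Acot3, a peroxisomal acyl-CoA thioesterase, and Vnn1, a pantetheinase, rose by 1.00 ± 0.15 and 1.23 ± 0.22 on the log2 scale (SE), again adjusted over the list alone. The Cyp4a, Acaa1 and Acot genes have close paralogs, and reads shared with them make their single values uncertain. The list passed limma's camera test with a preset correlation (adjusted p = 1.12e-17), but not with an estimated correlation (adjusted p = 0.538 with an estimated correlation). Without givinostat replicate 1, 8 members rose when adjusted over the list alone.

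Genes of fatty acid and triglyceride synthesis and storage were mixed, with 19 of 27 members higher and a median log2 fold change of 0.23. Adjusted over the list alone, 9 rose and 3 fell, against 0 over all genes by edgeR and 5 higher and 0 lower over all genes by DESeq2. Those that rose included Scd1, the stearoyl-CoA desaturase, at 3249 ± 19.1 CPM (SD, n = 2) against 1253 ± 95.2 CPM (SD, n = 3), Cidec, the triglyceride lipase Pnpla2 (0.82 ± 0.16, SE) and the fatty acid transporter Cd36 (0.72 ± 0.16, SE). Those that fell, named after their values were seen, were Acly, Scd2 and Srebf1, with log2 fold changes of -0.54, -0.72 and -0.60. Acly supplies cytosolic acetyl-CoA, and Srebf1 encodes a transcription factor of lipid synthesis. The camera adjusted p of the list was 0.00321, and the adjusted p was 0.538 with an estimated correlation. The number called over the list alone was 6 without CCl4 replicate 2, 3 without givinostat replicate 1, 4 without givinostat replicate 2 and 3 with the replicate number as a block, and the list median was 0.34 without CCl4 replicate 1 and 0.11 without givinostat replicate 2.

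Cholesterol synthesis genes lay on the other side. Of 24 members, 23 had a lower fitted value, the median log2 fold change was -0.71, and 17 fell when adjusted over the list alone, against 0 over all genes by edgeR and 7 by DESeq2. Idi1, the isopentenyl-diphosphate isomerase, averaged 5.88 ± 0.375 CPM (SD, n = 2) with givinostat and 21.6 ± 6.64 CPM (SD, n = 3) with CCl4. Cyp51, the lanosterol demethylase, fell by 1.32 ± 0.24, and Fdps, the farnesyl diphosphate synthase, by 1.07 ± 0.21 (log2, SE), adjusted over the list alone. For Fdps, 26.7% of the exonic bases overlap another gene model on the same strand. The camera adjusted p of the list was 9.94e-14, and the adjusted p was 0.542 with an estimated correlation. CCl4 replicate 1 stood between the other CCl4 libraries and the givinostat libraries, with a list score of -0.14 against 0.50 and 0.54 in CCl4 replicates 2 and 3 and -0.40 and -0.50 in the givinostat libraries. The count adjusted over the list alone was 5 without CCl4 replicate 2, 7 without CCl4 replicate 3, 2 without givinostat replicate 1, 0 without givinostat replicate 2 and 10 with the block.

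The 8 textbook readouts of stellate cell activation and scarring chosen before the data were examined all had negative fitted log2 fold changes, and none passed the edgeR threshold over all genes. Col1a1, the main fibrillar collagen chain, was at 22.2, 23.1 and 46.2 CPM in CCl4 replicates 1 to 3 and at 21.4 and 14.3 CPM with givinostat, a log2 fold change of -0.78 ± 0.35 (SE). Its exact two-sided permutation p over the 10 assignments of the libraries was 0.3, where 0.1 is the smallest these assignments can give. Col1a2, Col3a1, Acta2, Tgfb1, Pdgfrb and Des had log2 fold changes of -0.61, -0.42, -0.64, -0.43, -0.16 and -0.56, with edgeR adjusted p-values from 0.677 to 0.939. Every sign held with each library left out, but the sizes varied. Without CCl4 replicate 3, Col1a1, Col1a2, Col3a1 and Timp1 were at -0.34, -0.26, -0.03 and -1.26, and without givinostat replicate 2 Col1a1, Col3a1, Acta2, Tgfb1 and Pdgfrb were at -0.51, -0.10, -1.48, -0.65 and -0.25. Without givinostat replicate 1, Acta2 was at -0.12, Tgfb1 at -0.24, Pdgfrb at -0.07 and Col3a1 at -0.81, while Tgfb1 and Pdgfrb were at -0.65 and -0.06 without CCl4 replicate 1 and at -0.18 and -0.26 without CCl4 replicate 2. With the replicate number as a block, Col1a1, Col1a2 and Col3a1 were at -0.37, -0.27 and -0.08. Timp1, an inhibitor of matrix metalloproteinases, had the largest difference of the 8, with a log2 fold change of -1.90 ± 0.54 (SE; edgeR adjusted p = 0.413, and 0.0582 adjusted over the list alone). Timp1 was at 2.99, 3.08 and 8.16 CPM with CCl4 and at 0.983 and 1.53 CPM with givinostat. By the exact permutation test Timp1 had a p of 0.1, where the other readouts had 0.2 (Des) to 0.6 (Col3a1). It was also the only one of the 8 at an unadjusted edgeR p under 0.05 and the only one called by DESeq2 (adjusted p = 0.0375).

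**Figure D1:**
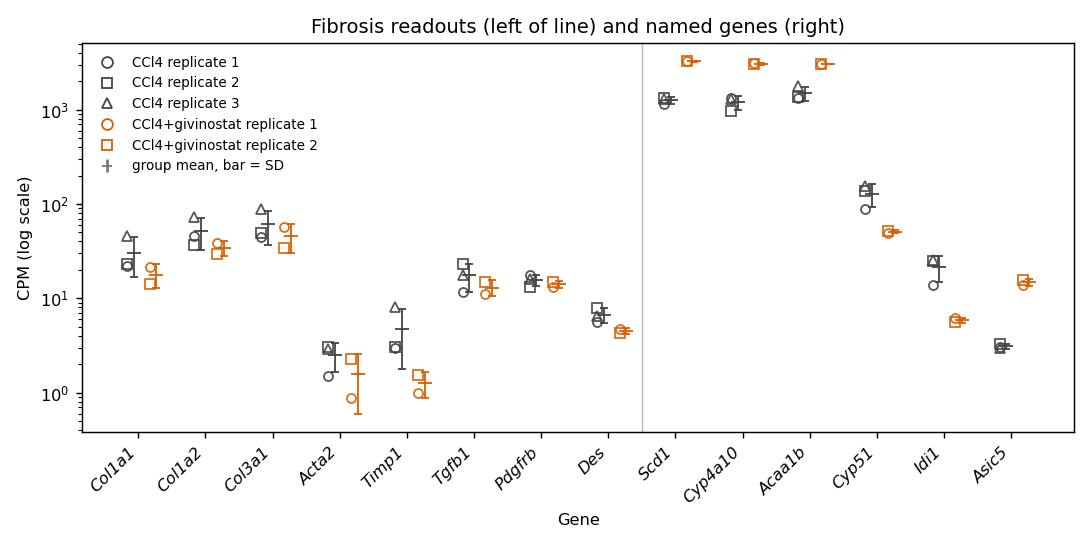
CPM (vertical axis, log scale) of 8 fibrosis readouts, left of the line, and 6 further named genes, right of it, in each library (open symbols) with the group mean and SD (bars; CCl4 n = 3 in grey, CCl4+givinostat n = 2 in orange). Col1a1 reached 46.2 CPM in CCl4 replicate 3 and 22.2 and 23.1 in the other CCl4 libraries. Both givinostat libraries lay above every CCl4 library for Scd1, Cyp4a10, Acaa1b and Asic5. They lay below every CCl4 library for Cyp51 and Idi1. The naming rule required this separation of Scd1, Cyp4a10, Asic5 and Idi1, and took Acaa1b and Cyp51 for a small p in their lists. Of all tested genes, 23.4% had groups without overlap, against 20% by chance.

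As groups, the genes around these readouts lay lower. Of 20 activated stellate cell and contractile genes, 19 had a lower fitted value (median log2 fold change -0.49; camera adjusted p = 2.93e-05, and adjusted p = 0.538 with an estimated correlation). The smallest p-values in that list belonged to Timp1, the actin-binding protein gene Tpm1 (-0.51 ± 0.15), S100a6 (-0.74 ± 0.27) and Spp1, the osteopontin gene (-0.67 ± 0.26, SE). No member passed edgeR's test over all genes or adjusted over the list alone, 6 were lower at an unadjusted p under 0.05, and DESeq2 called 2 over the list alone. Without CCl4 replicate 1, edgeR called 8 over the list alone. Vascular smooth muscle genes, of another contractile cell type, lay nearly as low (7 of 9 lower, median -0.45; camera adjusted p = 0.0568). They passed without CCl4 replicate 1 or givinostat replicate 2 (adjusted p = 0.0231 and 0.0181) and with a prior count of 5 in place of 2 in log2 CPM, tried after the data were seen (0.0499), and had a median of -0.12 without givinostat replicate 1. That list shares Acta2, Des and Tagln with the activated list, so the bulk values do not tell the cell types apart. Spp1 of the activated list also stands on the cholangiocyte list. Of 36 genes of fibrillar collagens and collagen-rich matrix, 30 had a lower fitted value (median -0.32; camera adjusted p = 7.07e-05, and adjusted p = 0.663 with an estimated correlation). Tnc, Aebp1, Emilin1 and Thbs1 led that list with log2 fold changes of -1.32 ± 0.34, -1.02 ± 0.34, -0.45 ± 0.15 and -0.65 ± 0.26 (SE). No matrix gene passed edgeR's test over all genes or the list alone, 7 were lower at an unadjusted p under 0.05, and DESeq2 called 0 over the list alone. CCl4 replicate 3 had the highest matrix score of the 5 libraries, and the list median was -0.14 without it and -0.17 without givinostat replicate 2. With the block the median was -0.16 and the list did not pass (adjusted p = 0.0584).

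Basement membrane genes had a median of -0.41, with 13 of 15 lower (camera adjusted p = 0.00214, and adjusted p = 0.542 with an estimated correlation). Nid2 and Col15a1 fell when adjusted over the list alone, by 1.10 ± 0.25 and 0.87 ± 0.21 on the log2 scale (SE), against 0 members over all genes by edgeR and these 2 by DESeq2. The count over the list alone was 0 without CCl4 replicate 2, without CCl4 replicate 3 and without either givinostat library, and 5 without CCl4 replicate 1, and camera did not pass with the block (adjusted p = 0.0663). Enzymes of collagen processing and crosslinking had a median of -0.25 (camera adjusted p = 0.0469, and adjusted p = 0.701 with an estimated correlation), a call lost without CCl4 replicate 3 (median -0.11) or givinostat replicate 2, with the block (median -0.12) and with a prior count of 0.5 (adjusted p = 0.0503). Quiescent stellate cell genes had a median of 0.02, with 12 of 20 higher (camera adjusted p = 0.991), and of -0.01 to 0.05 with each library left out. Among them Steap4, which also stands on the acute phase list, fell over the list alone by 0.82 ± 0.16 (log2, SE). EdgeR called 0 of these genes over all genes, and DESeq2 called Steap4. TGF-beta pathway genes had a median of -0.10 (camera adjusted p = 0.340), which was 0.04 without CCl4 replicate 1, 0.03 without givinostat replicate 1 and -0.21 without givinostat replicate 2. Metalloproteinases and their inhibitors had a median of -0.19 and did not pass (camera adjusted p = 0.0507, and 0.0452 with a prior count of 5). Their median was -0.10 without CCl4 replicate 3, -0.31 without givinostat replicate 1 and -0.36 without givinostat replicate 2.

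**Figure D2:**
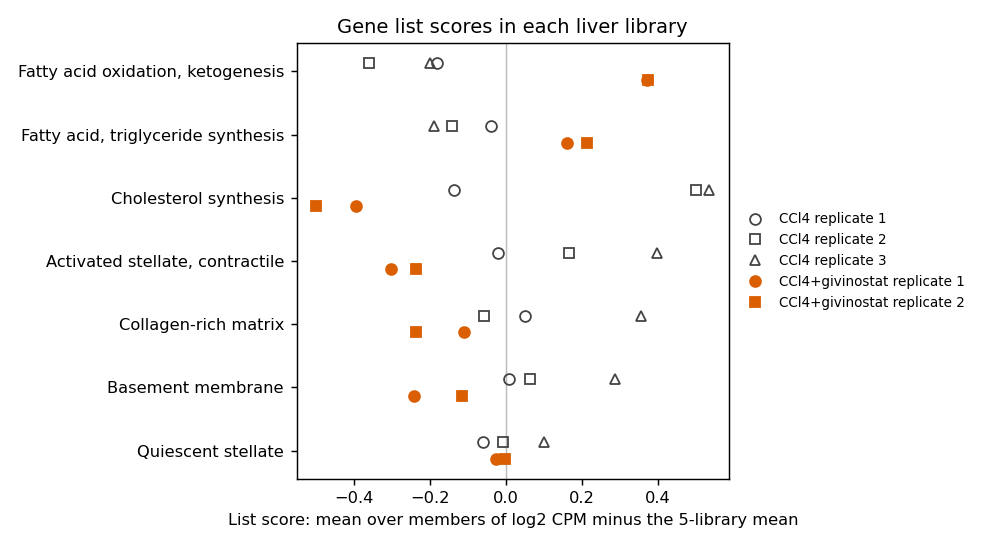
List score of 7 gene lists (vertical axis) in each library, the mean over members of log2 CPM minus the gene's mean over the 5 libraries (horizontal axis), with CCl4 libraries as open symbols (n = 3) and CCl4+givinostat libraries as filled symbols (n = 2). Both givinostat libraries scored 0.37 for fatty acid oxidation, above the CCl4 libraries at -0.36 to -0.18, and the matrix score of CCl4 replicate 3 was 0.36.

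Transcripts typical of mesothelial cells, which line the liver surface, lay far lower with givinostat. All 16 measured members had a lower fitted value, and 11 fell when adjusted over the list alone, against 0 over all genes by edgeR and 7 by DESeq2 (median log2 fold change -2.72; camera adjusted p = 2.26e-16, and adjusted p = 0.538 with an estimated correlation). Msln, the mesothelin gene, had 72, 24 and 54 counts in the CCl4 libraries and 0 and 1 counts with givinostat, a ratio of pooled depth-scaled counts of 105 (95% interval 18.5 to 4160, counting error only). Upk3b, Upk1b and Nkain4 were lower by ratios of 36.7, 20.2 and 12.4, with intervals of 12.3 to 180, 7.69 to 75.5 and 4.63 to 46.7. Others were lower by less, with ratios of 3.32 for Wt1, 2.36 for Krt19 and 2.29 for Cldn15. The givinostat libraries differed for Krt19 (35 and 7 counts) and Cldn15 (11 and 3 counts). Krt19 in givinostat replicate 1 lay above the 26 counts of CCl4 replicate 2. The CCl4 libraries differed among themselves as well. Over 14 of the genes, without C3 and Slc39a8, pooled CPM was 11.8 in CCl4 replicate 2 against 27.0 and 33.1 in CCl4 replicates 1 and 3, and 4.52 and 3.28 in the givinostat libraries. Without givinostat replicate 1, 7 members fell over the list alone.

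Markers of other liver cell types moved by smaller amounts and in both directions. Cholangiocyte genes had a median log2 fold change of -0.20 (14 of 19 lower; camera adjusted p = 0.00513, and adjusted p = 0.622 with an estimated correlation), and Prom1 (-1.44 ± 0.29) and Pkhd1 (-0.95 ± 0.21, SE) fell when adjusted over the list alone and by DESeq2 over all genes. The cholangiocyte median was -0.36 without CCl4 replicate 2 and -0.31 without givinostat replicate 2 or with no low-count filter. Portal fibroblast genes had a median of -0.23 (12 of 15 lower; camera adjusted p = 0.0221, and adjusted p = 0.542 with an estimated correlation), lost without CCl4 replicate 3 (median -0.14) or givinostat replicate 2 and with the block. Kupffer cell genes, from the resident macrophages, had a median of -0.33 (17 of 18 lower; camera adjusted p = 0.0351, and adjusted p = 0.788 with an estimated correlation), lost without CCl4 replicate 2 (median -0.16) or givinostat replicate 1. Sinusoidal and vascular endothelial genes had medians of -0.27 and -0.25 (camera adjusted p = 0.0221 and 0.0351, and adjusted p = 0.792 and 0.788 with an estimated correlation). Their direction rested on givinostat replicate 1, without which the medians were 0.18 and 0.10. The sinusoidal list then passed camera in the higher direction (adjusted p = 0.0444) and the vascular list did not pass (0.351), and both calls were also lost without CCl4 replicate 2 (medians -0.12 and -0.14) or CCl4 replicate 3. The medians were -0.45 and -0.42 without CCl4 replicate 1 and -0.92 and -0.88 without givinostat replicate 2. Of 6 erythroid genes, 6 were higher (median 0.51, camera adjusted p = 0.00421, and adjusted p = 0.538 with an estimated correlation). The estimate for that list was -0.106, below the preset 0.01. The erythroid median was 0.34 without CCl4 replicate 1 and 0.27 without givinostat replicate 1. T and NK cell genes (median -0.38, 13 of 17 lower) and monocyte-derived macrophage genes (median -0.25, 14 of 21 lower) did not pass camera (adjusted p = 0.0571 and 0.207). Both passed as lower without CCl4 replicate 1 (adjusted p = 0.0446 and 0.000207), and T and NK cell genes also without CCl4 replicate 3 (0.000177). Neutrophil genes (median 0.41, 9 of 14 higher) and B and plasma cell genes (median 0.32, 8 of 14 higher) did not pass camera (adjusted p = 0.0585 and 0.286). The neutrophil list passed as higher without CCl4 replicate 2, CCl4 replicate 3 or givinostat replicate 1 (adjusted p = 8.37e-05, 0.0284 and 0.0442), while without CCl4 replicate 1 its median was 0.01 and camera gave the direction as down. The B and plasma cell list passed as higher without givinostat replicate 1 (adjusted p = 0.0328) and had a median of 0.17 without CCl4 replicate 2 and -0.02 without givinostat replicate 2.

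None of Hdac1 to Hdac11 passed edgeR's test over all genes, none had an unadjusted p under 0.05, and DESeq2 called 0. Of the 11, 9 had a negative log2 fold change (median -0.22; camera adjusted p = 0.0507), and Hdac9 had the largest at -0.82 ± 0.39 (SE). The list passed as lower without CCl4 replicate 1 (adjusted p = 0.0404) and with a prior count of 5 (adjusted p = 0.0452). Of 21 genes reported to rise under inhibitors of these enzymes in other systems, 10 were higher and 11 lower (median -0.03, mean -0.05, while camera gave the direction as up; adjusted p = 0.678). Their median was -0.04 to 0.06 with each library left out. Glrx and Txnip rose and Klf2 fell when adjusted over the list alone, by 0.82 ± 0.14, 0.96 ± 0.26 and -1.07 ± 0.30 on the log2 scale (SE), against 0 over all genes by edgeR and 1, Glrx, by DESeq2.

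Drug-metabolising enzymes did not pass as a group, with 21 of 39 higher and a median log2 fold change of 0.13 (camera adjusted p = 0.0527). The list passed as higher without CCl4 replicate 2 or givinostat replicate 2 (adjusted p = 0.0417 and 0.00384) and with a prior count of 5 (0.0452), and its median was -0.04 without givinostat replicate 1. Adjusted over the list alone, 9 rose and 1 fell, against 0 over all genes by edgeR and 6 higher and 1 lower by DESeq2. The total over the list alone was 5 without CCl4 replicate 2 and 3 without givinostat replicate 1. Cyp2e1, the cytochrome P450 that turns CCl4 into its reactive radical, was at 859, 1038 and 984 CPM with CCl4 and at 3040 and 1639 CPM with givinostat (log2 fold change 1.28 ± 0.25, SE). Cyp4a14 and Cyp2b10 rose by 1.33 ± 0.24 and 1.26 ± 0.22 (SE), and Cyp1a2, the one that fell, had a log2 fold change of -1.20 ± 0.35 (SE). Beyond the hepatocyte lists, ribosomal protein genes (40 of 40 higher, median 0.19) and oxidative phosphorylation genes (34 of 36, median 0.23) passed camera with adjusted p-values of 1.73e-06 and 3.89e-06, and adjusted p was 0.691 for both with an estimated correlation. Both calls were lost without givinostat replicate 1, with medians of 0.09 and 0.06, and without givinostat replicate 2 the medians were 0.31 and 0.40. In all, 7 of 53 lists passed in the higher direction and 14 in the lower direction with the preset correlation, and 0 passed with an estimated correlation or with limma's fry.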

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

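Counts of genes adjusted over a list alone under the alternatives, and other prior counts, were added only after the data were seen, and all other alternatives were fixed beforehand. The number of genes called in edgeR depended on the setting. It was 68 higher and 77 lower with the replicate number as a block, 23 and 15 with no low-count filter, 0 and 0 with the stricter filter, 69 and 79 by DESeq2 (no adjusted p was missing), and 2 and 1 at an adjusted p of 0.1. RLE scaling and the minimum log2 fold change of 1 left the counts at 1 and 0. Leaving out each library gave 0 to 119 higher and 0 to 116 lower, the maximum without CCl4 replicate 1 and 0 without each of the other 4. A lone givinostat library was then assumed to vary like the CCl4 libraries. DESeq2 shared 94 of its 148 genes with edgeR without CCl4 replicate 1 and 76 with the block, all with the same sign. Of the 8 fibrosis readouts DESeq2 called 1, Timp1, and every edgeR setting called 0. The cause was not tested.

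With the preset correlation, 7 lists passed as higher and 14 as lower, and leaving out each library gave 7 to 10 and 9 to 23. With an estimated correlation both counts were 0 (smallest adjusted p 0.538), and with fry 0 (smallest 0.122). The collagen-rich matrix median of -0.32 and the activated stellate median of -0.49 are unchanged by those tests but no longer past the threshold. With the block the matrix median was -0.16 and not past the threshold. Leaving out each library gave -0.34 to -0.14 for matrix and -0.60 to -0.41 for activated stellate genes, past the threshold each time. The medians of sinusoidal and vascular endothelial genes ranged from -0.92 to 0.18 and from -0.88 to 0.10, with the sign turned without givinostat replicate 1, where the sinusoidal list passed as higher. The cause was not tested.

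Whether the replicate numbers pair the libraries is not known. Deviations of same-numbered libraries from their group means correlated at -0.148 and -0.0753 across genes. The deviations of the 2 givinostat libraries are mirror images of each other, so these values cannot exclude pairing. CCl4 replicate 3 is alone in its block, so the blocked counts are given as a description. The planned change of pseudocount, written for normalized values, was not run. Camera uses log2 CPM with a prior count of 2, and a prior count of 0.5 gave 7 lists higher and 13 lower, and 5 gave 10 and 20, with the matrix and activated stellate lists past the threshold each time. The mesothelial median difference in log2 CPM was -2.39 with 0.5 and -1.76 with 5. At these depths a count of 0 allows up to 0.156 CPM, which limits ratios for mesothelial genes.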

Other observations

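Hepatocyte and immune lists outside the fibrosis question gave mixed results. Fga, Fgb and Fgg, which encode the fibrinogen chains, fell when adjusted over the list of hepatocyte secreted proteins alone, with log2 fold changes of -0.92 ± 0.18, -0.75 ± 0.18 and -0.79 ± 0.16 (SE), and DESeq2 called these 3 over all genes, while that list as a whole did not pass (camera adjusted p = 0.264, and 0.0464 as lower without CCl4 replicate 1). Among acute phase genes, Saa3, Cp and Steap4 fell and Hamp2 rose over the list alone, DESeq2 called Cp, Steap4 and Hamp2 over all genes, and the list did not pass (camera adjusted p = 0.0507). It passed as lower without CCl4 replicate 1, CCl4 replicate 3 or givinostat replicate 1 (adjusted p = 0.0404, 0.0301 and 0.0132) and with a prior count of 5 (0.0452). The count of 4 genes was 13 without CCl4 replicate 1, 1 without givinostat replicate 1 and 0 without givinostat replicate 2. Complement and coagulation genes had a median log2 fold change of -0.18 (27 of 31 lower) and chemokine and cytokine genes -0.31 (20 of 27 lower), with camera adjusted p-values of 0.00730 and 0.00813, and adjusted p was 0.691 for both with an estimated correlation. The complement call was lost without CCl4 replicate 2 (median -0.08) or givinostat replicate 2 and with the replicate number as a block. The chemokine call was lost without CCl4 replicate 3 (median -0.16) or givinostat replicate 1 (median -0.19), and the median was -0.14 with the block.

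Clock genes passed camera as higher (median 0.21; adjusted p = 0.0158, and adjusted p = 0.542 with an estimated correlation), lost without CCl4 replicate 3 or givinostat replicate 1 and with the block. The median was 0.34 without CCl4 replicate 1 and 0.08 without CCl4 replicate 2. Over the list alone, Tef rose by 0.86 ± 0.16 and Bhlhe40 fell by 0.92 ± 0.24 (log2, SE), both also called by DESeq2 over all genes. Bnip3, a mitophagy receptor gene, rose over the glycolysis and hypoxia list alone by 1.00 ± 0.14 (log2, SE), and DESeq2 called it over all genes, with camera adjusted p = 0.737 for that list. A1bg averaged 43.2 ± 20.2 CPM (SD, n = 3) with CCl4 and 6.28 ± 2.35 CPM (SD, n = 2) with givinostat. Replication-dependent histones (median -0.38; camera adjusted p = 0.0221, and adjusted p = 0.542 with an estimated correlation) and unfolded protein response genes (median 0.07; adjusted p = 0.0412, and adjusted p = 0.691 with an estimated correlation) passed as lower and higher, and both were lost without CCl4 replicate 2 or givinostat replicate 2 and with no low-count filter. Only 7 of the 28 listed histone genes were tested, and 1 of them had an unadjusted edgeR p under 0.05. The histone median was -0.59 without CCl4 replicate 1. The unfolded protein median was 0.02 without CCl4 replicate 2, 0.12, 0.19 and 0.11 without CCl4 replicate 1, CCl4 replicate 3 and givinostat replicate 1, and 0.20 with the block. Interferon response genes did not pass (camera adjusted p = 0.450). They passed as higher without CCl4 replicate 3 (median 0.38; adjusted p = 6.00e-07) and as lower without CCl4 replicate 1 (median -0.53; adjusted p = 0.00124), and the size of their median reached 0.94 in another split of the 5 libraries.

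The tests of fasting, time of day, depth, liver surface and stellate cell number, and the counts of splits, were set out after the results were seen, and the tests of length and GC content before, except that of the activated stellate list. The 5 libraries can be split 3 against 2 in 10 ways, too few for a share under 0.05. Splits that set 2 CCl4 libraries against the rest keep both givinostat libraries together, so a treatment difference can add to their values. For genes past the threshold, 2 of the 10 splits gave at least the real count of 1, and the highest other split gave 5, when CCl4 replicates 2 and 3 were set against the rest. For lists, 3 of the 10 gave at least the real 21, and the highest other gave 29. The split of CCl4 replicates 2 and 3 against the rest follows the first principal component. On it CCl4 replicate 1 lay at -33.95, CCl4 replicates 2 and 3 at 19.51 and 34.99, and the givinostat libraries between, at -6.465 and -14.08. Both givinostat libraries stand with CCl4 replicate 1 in that split, so differences among CCl4 libraries and a treatment difference are mixed in it. For fatty acid oxidation, 1 of the 10 splits, the real one, gave a median as large as 0.46, and the highest other gave 0.39. For cholesterol synthesis 2 of the 10 gave a median as large in size as -0.71, the highest other 0.89, and for activated stellate genes 2 of the 10 as large as -0.49, the highest other 0.54. For mesothelial genes 1 of the 10, the real one, was as large as -2.72 and the highest other was 2.18, and for the collagen-rich matrix 1 of the 10 as large as -0.32 and the highest other 0.30. By camera p, another split gave a smaller value than the real one for cholesterol synthesis (4.81e-18 against 5.62e-15). The same held for mesothelial genes (2.49e-20 against 8.52e-18) and the matrix (2.11e-09 against 9.34e-06). The cholesterol value came from CCl4 replicates 2 and 3 against the rest, and the mesothelial value from CCl4 replicates 1 and 3 against the rest. Both splits keep the givinostat libraries together, so they are not free of a treatment difference.

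Higher fatty acid oxidation with lower cholesterol synthesis is the first pattern of interest. A bias with transcript length or GC content is argued against, since removing both trends in each library left a median of 0.481 for the oxidation list and -0.650 for the cholesterol list. On the same measure, the difference of mean log2 CPM, these medians were 0.46 and -0.681 before removal. Longer fasting of the givinostat mice may contribute: 12 genes that fall on fasting had a median log2 fold change of -0.135 with an SD of 0.813, 5 higher and 7 lower, which does not decide it. A different time of day could also contribute, as the clock gene contrast was 0.544 higher with givinostat, with both givinostat libraries (0.458 and 0.195) above every CCl4 library (highest 0.156), but the CCl4 libraries alone spanned 0.818, so this is not decided. An effect of the drug on hepatocytes stays open with these.

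The lower level of mesothelial transcripts is the second. Lower depth is excluded, as the effective library size with givinostat was 1.05 times that with CCl4. The pieces of liver may have held different amounts of surface: pooled CPM over 14 mesothelial genes differed 2.80-fold between CCl4 libraries, less than the 6.15-fold between the group means. Without Krt19 and Cldn15 as well, left out after the data were seen, these were 2.89 and 8.20, so uneven sampling and a treatment effect on the surface cannot be told apart with 2 givinostat libraries. Of the 16 listed genes, C3 and Slc39a8 are also abundant in liver at large, with pooled ratios of 1.16 and 1.07, and C3 and Krt19 stand on other lists too.

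The third is the lower level of activated stellate cell and matrix genes. In these libraries the quiescent stellate genes as a list did not fall with the activated ones, although 1 of them, Steap4, fell over the list alone. The quiescent list median lay 0.505 above the activated one, beyond the SD of 0.358 over the quiescent genes. For the collagen-rich matrix list the gap was 0.334, within that SD. That SD does not measure variation between mice. In another split of the 5 libraries the activated median reached 0.54 in size, while no other split took the quiescent median beyond 0.105 in size. The activated list also shares genes with vascular smooth muscle, and Spp1 with the cholangiocyte list. Fewer stellate cells and lower expression per cell therefore cannot be told apart for either list. Removing length and GC trends left the activated median at -0.430 (95% interval -0.675 to -0.347), which argues against such a trend there. It covers the 18 of 20 genes with a known length, and their median difference of mean log2 CPM was -0.446 before removal. Removing the trends left the matrix median at -0.229 (95% interval -0.376 to -0.0766), from -0.291 before on the same measure. That neither ends the difference nor excludes such a trend as part of it. Both intervals come from resampling the genes of a list, so they leave out variation between mice. An effect of givinostat on stellate activation stays open.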
